A study of Homo sapiens with 4 samples.

How the data were processed

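Small RNA libraries were made from MDA-MB-231 and MCF-10A cells and from exosomes purified from their cultures, 1 library for each of the 4 groups. Per the labels' protocols, MDA-MB-231 was grown with 10% fetal bovine serum and MCF-10A with 5% horse serum. RNA was extracted with TRIzol reagents, small RNAs of 17 to 52 nt were size-selected, and libraries were ligated at the 5′ monophosphate and sequenced on a Genome Analyzer IIx, per the labels' protocols. Novoalign, edgeR and the build hg18 are named in the submitters' processing notes, with no version and no role given. How exosomes were purified, how reads were assigned to miRNA names, and the miRBase release were not given in the sources used here.

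The deposited values of each library are on a log2 scale, with 2 decimals, for 1100 mature miRNA names. The authors' log base and scale were worked out from the values: 2 to the power of the value, minus 1, sums to about 10000000 in each library (9992361 to 10004141), and the low values are whole multiples of 1 step. The values were therefore read as log2 of reads per 10000000 miRNA reads plus 1, where 0 is 0 reads. The step, which is the worth of 1 read, was 6.52 reads per 10000000 in MDA-MB-231 exosomes, 1.36 in MDA-MB-231 cells, 7.97 in MCF-10A exosomes and 0.914 in the library labelled MCF-10A cell, which gave the depths 1532909, 7346080, 1254641 and 10937870 reads. Of the nonzero names, 65.7%, 55.7%, 65.6% and 40.1% were low enough for the rounding to resolve single reads (a rounding interval under 0.5 reads wide), and for 100% of those a whole number of reads lay within that interval, at a step chosen to give the most of them. Larger read numbers are known only to the deposited rounding of 0.005 log2, or 0.347%. A count of 0 allows up to 3 reads, which is 19.6, 4.08, 23.9 and 2.74 reads per 10000000 in the same order.

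The design had assumed read counts. Because the deposited unit was a log scale, the fold of the main result is the difference of the deposited log2 values (pseudocount 1 per 10000000), and it understates the fold of names with few reads but can exceed what the reads support for names at 0, for which bounds are given. The count rule fixed in advance was run on the recovered reads as an alternative chosen after the data were seen. A name entered a comparison with at least 10 reads per 10000000 in 1 of the libraries compared, and it counted as higher or lower at a log2 difference of 2, a 4-fold size. The comparisons were MDA-MB-231 against MCF-10A in exosomes and in cells, exosomes against cells in each line, and the difference between the last pair. Ratios have exact conditional binomial 95% intervals on the recovered reads, and shares of reads have Wilson 95% intervals. With 1 library per group there was no test across replicates, and a model with additive terms for line and fraction, which would leave 1 residual degree of freedom, was not run. The read rule named in the text asks for at least 10 recovered reads in 1 library and a counting interval that excludes no difference.

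The lists of miRNAs were fixed before the data were examined. They cover the miR-200, let-7, miR-15/16, miR-29, miR-30, miR-34 and miR-449, miR-181, miR-130 and miR-301, miR-148 and miR-152 and miR-320 families. They also cover the miR-183-96-182, miR-221 and miR-222, miR-105 and miR-767, miR-17-92, miR-23/27/24, miR-193 and miR-365 and miR-224 and miR-452 clusters, the miR-99/100 and miR-125 group, miR-146 with miR-155, Hox-cluster miRNAs, skin and basal epithelium miRNAs, and the hypoxia miRNA miR-210. Reported promoters and suppressors of breast cancer metastasis, names later linked to fragments of other RNAs, and passenger arms (names with a star) were lists as well. Lists of other tissues were mesenchymal, endothelial, erythroid, leukocyte, liver, muscle, neural, and intestine, kidney and pancreas miRNAs, and the 14q32, 19q13 and Xq27 clusters, 11 in all, beside embryonic stem cell miRNAs. A list's median was placed among 10000 random lists of the same size matched on mean level, for lists of 3 or more names, as a description of these libraries. Names at 0 in 1 library enter the median at the value with the pseudocount, and again at their 3-read bound, leaving out those at or under the bound in both libraries.

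Named miRNAs followed a rule fixed in advance: the 8 highest and 8 lowest folds of each comparison among names with at least 50 reads per 10000000 in 1 library, the 5 highest and 5 lowest for the difference, the 10 most abundant of each library, up to 4 members of any list with the highest mean level, lists with under 3 measured members in full, and miR-105, miR-122 and miR-210 in every library. Names outside it are said to be chosen after their values were seen. The prefix for human is left out of the names. In 11 sets, 28 names with 50 or more reads share the same value in all 4 libraries, as mature sequences encoded at more than 1 place do, and such names were counted 1 by 1.

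The alternatives chosen in advance were scaling by TMM (trims of 30% and 5%), median of ratios or upper quartile, totals without the 5 most abundant names, minimums of 50 or none, pseudocounts of 0.1 and 5, sizes of 2-fold and 8-fold, leaving out names linked to fragments, and thinning to the smallest library. All computing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and scalings were computed in numpy. The recovery of reads and the rules were tested on simulated libraries of 1100 names with the real depths, and names under 50 reads were recovered exactly in 100% of cases. For MDA-MB-231 against MCF-10A exosomes, 90.0% of names changed 8-fold and 99.0% of those changed 32-fold were called, with 27 of 900 unchanged names past 4-fold. The shares at 8-fold were 99.0% for the cell comparison, 95.0% for exosomes against cells in MDA-MB-231 and 63.0% in MCF-10A, with 0, 21 and 51 of 900 unchanged names past 4-fold. The changed names were drawn only from names past the minimum, whereas the 900 unchanged names included those under it, which are rarely called. Counts out of 900 therefore understate the share of false calls among names past the minimum, which was not computed. Coordinates come from GRCh38 in GENCODE release 29 by gene name, because the files give none.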

Results

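Small RNA was sequenced from cultured cells and from exosomes purified from their cultures, in a pair of human breast lines. MDA-MB-231 is a triple-negative breast cancer line with mesenchymal features that forms metastases in mice. MCF-10A is a non-transformed mammary epithelial line. Exosomes are small vesicles that cells release and that carry RNA. Each of the 4 groups (exosomes and cells of each line) held 1 library, so no difference below had a replicate check, and no p-value was computed. The deposited values covered 1100 mature miRNA names per library. Whole reads recovered from them gave 1532909 miRNA reads for MDA-MB-231 exosomes, 7346080 for MDA-MB-231 cells, 1254641 for MCF-10A exosomes and 10937870 for the library labelled MCF-10A cell. The names above 0 numbered 508, 566, 436 and 794 in that order, 355 were above 0 in every library, and 258 were at 0 in every library. Levels are given as deposited, as log2 of reads per 10000000 plus 1. Folds between libraries carry a 95% counting interval in parentheses. A fold against 0 reads, given as at least, sets that library at 3 reads and takes the reads of the other library as exact. It is therefore not a 95% lower limit, which lies lower (for miR-105 between exosomes, 14.9-fold beside 18.9-fold). Intervals and bounds cover counting error at most, because reads made by PCR without molecular identifiers are not independent molecules.

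miR-21, an oncogenic miRNA encoded at the VMP1 gene, was the most abundant name in 3 of the 4 libraries. It took 37.8% of the reads of MDA-MB-231 exosomes (Wilson 95% interval 37.7 to 37.9), 40.3% of MDA-MB-231 cells (40.2 to 40.3) and 30.5% of MCF-10A exosomes (30.4 to 30.6), against 7.79% (7.77 to 7.80) of the library labelled MCF-10A cell. In MDA-MB-231 exosomes it was followed by let-7a (8.22%), miR-30a (6.19%), miR-100 (5.06%), miR-146a (4.06%), let-7f (3.27%), let-7b (3.12%), miR-1246 (3.12%), miR-30d (2.22%) and miR-24 (2.10%). MDA-MB-231 cells shared 7 of these 10 names, with let-7a at 9.72% and miR-30a at 9.07%, and held miR-378 (2.46%), miR-103 (1.66%) and miR-27a (1.56%) in place of miR-146a, let-7b and miR-1246. MCF-10A exosomes also shared 7, with let-7a at 18.9% and let-7b at 10.9%, and added the epithelial miR-200c (3.76%), miR-378 (3.14%) and miR-182 (2.93%). The tumour-suppressive let-7 family together held 16.2% of the reads of MDA-MB-231 exosomes, 16.7% of MDA-MB-231 cells, 36.4% of MCF-10A exosomes and 6.07% of the library labelled MCF-10A cell. That library was led by miR-143 (27.1%), a miRNA of smooth muscle and fibroblasts, and by miR-1 (11.5%), a miRNA of skeletal and cardiac muscle. It also held miR-26a (3.23%), miR-126 (2.09%), miR-29a (1.58%) and the pair miR-199a-3p and miR-199b-3p (1.66% each), which share 1 sequence. Its 10 leading names had 3 in common with MDA-MB-231 exosomes, 3 with MDA-MB-231 cells and 2 with MCF-10A exosomes.

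Across names past the minimum, the levels of MDA-MB-231 exosomes and MDA-MB-231 cells had a Pearson r of 0.731 and a Spearman rho of 0.702 (499 names). The r was 0.666 between the exosomes of the lines (505 names) and 0.710 between MDA-MB-231 cells and MCF-10A exosomes (482 names). It was 0.440 between MCF-10A exosomes and the library labelled MCF-10A cell (661 names), 0.429 between that library and MDA-MB-231 cells (665 names), and 0.569 between that library and MDA-MB-231 exosomes (656 names). These correlations run across miRNAs, which are not independent replicates.

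The library labelled MCF-10A cell stood apart by miRNAs of tissues other than breast epithelium. The 11 lists of such miRNAs held 52.2% of its reads, against 2.75% in MDA-MB-231 exosomes, 0.180% in MDA-MB-231 cells and 0.158% in MCF-10A exosomes. In it, 153 of the 157 listed names had 10 or more reads, against 42, 20 and 18 in the other libraries in that order. Summed over the muscle list (miR-1, miR-133, miR-206, miR-208 and miR-499), it held 1243188 reads per 10000000, against 10.9 in MDA-MB-231 cells and 15.9 in MCF-10A exosomes. The neuronal miR-124 stood at 13.54 there and at 0 in MDA-MB-231 cells. miR-517a, of the placental cluster at 19q13, stood at 14 there and at 0 in MDA-MB-231 cells and MCF-10A exosomes. Every comparison below that uses this library contains this difference in content, and no other library of MCF-10A cells was analysed here. Levels are shares of all miRNA reads, so reads on these lists also lower the levels of all other names in this library. Folds above it would be smaller over the reads outside the lists, and such folds were not computed.

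**Figure D1:**
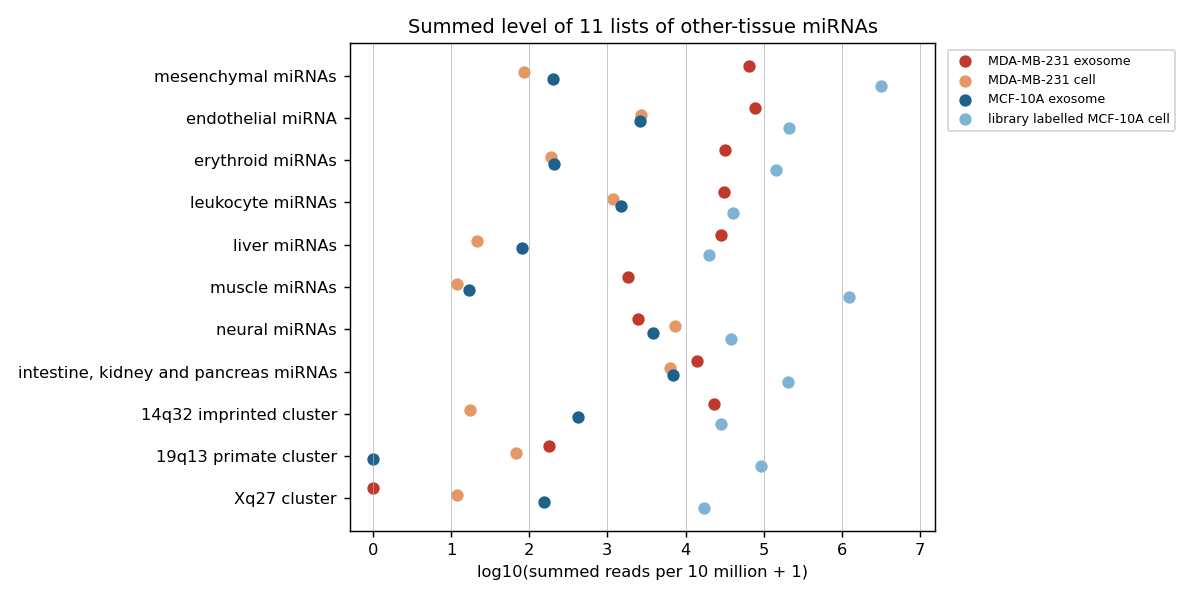
Summed level of 11 lists of miRNAs typical of other tissues, as log10 of reads per 10000000 plus 1 on the horizontal axis, with 1 point per library and 1 line per list. The library labelled MCF-10A cell lies highest for 10 of the lists, all but the liver list (19780 reads per 10000000 against 28341 in MDA-MB-231 exosomes).

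miR-105, miR-122 and miR-210 were chosen in advance because work on these lines is known to concern them. miR-105 stood at 8.82 in MDA-MB-231 exosomes and 9.59 in MDA-MB-231 cells, against 0 in MCF-10A exosomes and 4.27 in the library labelled MCF-10A cell. Its exosomal level was thus at least 18.9-fold higher in MDA-MB-231 than in MCF-10A (69 against 0 reads), and its cellular level 42.1-fold higher (27 to 69.4). Its neighbour miR-767-5p was at least 7.07-fold higher in MDA-MB-231 exosomes (26 against 0 reads) and 161-fold higher in MDA-MB-231 cells (68.7 to 499). miR-122, the main miRNA of liver, stood at 14.79 in MDA-MB-231 exosomes, 4.42 in MDA-MB-231 cells, 6.33 in MCF-10A exosomes and 14.26 in the library labelled MCF-10A cell. It was 357-fold higher in MDA-MB-231 than in MCF-10A exosomes (193 to 742) and 1388-fold higher in MDA-MB-231 exosomes than in MDA-MB-231 cells (840 to 2481). miR-210, which hypoxia induces, stood at 10.88, 9.2, 9.57 and 10.74 in the same order of libraries. It was 2.48-fold higher in MDA-MB-231 than in MCF-10A exosomes (1.97 to 3.17) and 3.21-fold higher in MDA-MB-231 exosomes than cells (2.76 to 3.74). Against the library labelled MCF-10A cell, miR-210 was 2.91-fold lower in MDA-MB-231 cells and 2.25-fold lower in MCF-10A exosomes, and both of these turned to higher under upper-quartile scaling.

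The files give no coordinates, and those here are of GRCh38 in GENCODE release 29, matched by gene name. miR-105 has copies on chromosome X at 152392219 to 152392299 (MIR105-1) and at 152394412 to 152394492 (MIR105-2), with MIR767 between them at 152393421 to 152393529, all on the minus strand within an intron of GABRA3. MIR122 lies on chromosome 18 at 58451074 to 58451158, overlapping an exon of MIR122HG, and MIR210 on chromosome 11 at 568089 to 568198, in an intron of MIR210HG. MIR200C and MIR141 lie 1 after the other on chromosome 12, at 6963699 to 6963766 and 6964097 to 6964191, in an intron of MIR200CHG. MIR205 overlaps an exon of MIR205HG on chromosome 1 at 209432133 to 209432242, and MIR31 lies in an intron of MIR31HG on chromosome 9 at 21512115 to 21512185. MIR146A overlaps an exon of MIR3142HG on chromosome 5 at 160485352 to 160485450. MIR21 lies on chromosome 17 at 59841266 to 59841337, overlapping an exon of VMP1, and MIR1246 on chromosome 2 at 176600980 to 176601052, outside annotated genes on its strand.

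The first comparison asked which miRNAs differ between the exosomes of the cancer line and those of the non-transformed line. Exosomes of MDA-MB-231 were poor in miRNAs of the epithelial state. All 5 members of the miR-200 family, which represses the ZEB factors and holds cells in an epithelial state, were at least 4-fold lower in MDA-MB-231 exosomes. miR-200c was 428-fold lower (361 to 509), miR-141 370-fold (232 to 638), miR-200b 10.1-fold (7.99 to 13) and miR-200a 5.95-fold (4.55 to 7.87). All 3 measured miRNAs of skin and basal epithelium were lower too. miR-205, a marker of basal mammary epithelium, had 2 reads against 1515 (927-fold, 256 to 7649), miR-203 was 16.4-fold lower (11 to 25.8), and miR-31 had 0 reads against 129, at least 52.6-fold lower. The 3 members of the miR-183-96-182 cluster were also lower, miR-182 by 8.82-fold (8.56 to 9.08), miR-183 by 5.03-fold (4.84 to 5.23) and miR-96 by 9.67-fold (7.25 to 13). The median log2 folds of these lists were −3.34, −9.75 (−5.72 with miR-31 at its bound) and −3.14, at percentiles 0.0250, 0.0350 and 0.660 of 10000 random lists matched on level. Further names with the lowest folds were miR-141* (0 against 117 reads, at least 47.8-fold lower), miR-335* (299-fold, 82.3 to 2474), miR-187 (at least 15.5-fold) and miR-205* (at least 7.31-fold).

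Higher in MDA-MB-231 exosomes was miR-146a, a target of NF-κB signalling, at 18.63 against 7.01, or 3172-fold (1959 to 5566). miR-155, another miRNA of inflammatory signalling, was 31.4-fold higher (15.1 to 79.0), while miR-146b-5p was 2.36-fold lower (2.15 to 2.60). The median of this list was 4.95 (percentile 97.6), the value of miR-155 itself, which had 269 reads in MDA-MB-231 exosomes and 3 in MDA-MB-231 cells. All 4 members of the miR-181 family were at least 4-fold higher (median 3.23, percentile 99.0), with miR-181a at 4.53-fold (4.35 to 4.72), miR-181b at 7.11-fold (6.75 to 7.49) and miR-181d at 19.7-fold (10.5 to 41.3). Among the Hox-cluster miRNAs, miR-10a was 31.6-fold (27.6 to 36.4) and miR-10b, a reported promoter of metastasis, 91.6-fold higher (61.6 to 144), while miR-196b was 28.8-fold lower (18.9 to 46.6). Like miR-155, miR-10b had many reads in MDA-MB-231 exosomes (2692) but few in MDA-MB-231 cells (16), so its source stays open. In the miR-15/16 family miR-503 was 36.3-fold (22.2 to 64.0) and miR-424 8.74-fold higher (5.60 to 14.4), with miR-16 within 4-fold. miR-30a was 5.78-fold (5.67 to 5.88) and miR-27b 4.96-fold higher (4.79 to 5.14). Of the names with the highest folds, miR-886-5p (at least 576-fold) is a name later linked to vault RNA, and miR-1270 (103 against 0 reads) was at least 28.0-fold higher.

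MDA-MB-231 exosomes were also richer than MCF-10A exosomes in miRNAs of blood, liver and stroma. All 4 erythroid names were higher, with miR-451 at 4137 against 2 reads (1696-fold, 468 to 13984) and miR-486-5p at 26.9-fold (17.5 to 43.9). All 4 leukocyte names were higher as well, with miR-142-3p at 23.4-fold (19.7 to 27.9), miR-150 at 7.99-fold (5.05 to 13.4) and miR-223 at 11.8-fold (6.84 to 21.9). The medians were 4.19 and 3.99, at percentiles 99.3 and 98.0. In the imprinted cluster at 14q32, 24 names were at least 4-fold higher, 2 lower and 3 within, and by recovered reads 15 were higher and 0 lower. There miR-127-3p had 913 against 0 reads (at least 249-fold), miR-432 178 against 0 (at least 48.5-fold), miR-494 72 against 0 (at least 19.7-fold), and miR-379 was 58.9-fold higher (37.0 to 99.4). Outside the list, miR-493*, the passenger arm to its member miR-493, had 283 against 0 (at least 77.2-fold). The cluster's median was 5.54, or 1.82 with names at 0 set at their bound. The mesenchymal list (6 of 6 higher, median 7.80, or 5.75 at the bounds) was led by miR-143 at 340-fold (223 to 551), and the endothelial miR-126 was 29.3-fold higher (26.2 to 32.7). Of the muscle list 4 of 4 were higher, 2 of them by recovered reads, with miR-1 at 106-fold (28.9 to 876) and a median of 5.69, or 1.71 at the bounds. Both liver names were higher, miR-122 as above and miR-885-3p with only 2 against 0 reads, for a median of 6.13.

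Most other lists of the exosome comparison differed less, and those with the largest medians rested on few reads. The let-7 family had 1 higher and 8 within 4-fold, with let-7a 2.30-fold and let-7b 3.51-fold lower, and its median of 0.09 turned negative under every other scaling. The miR-30 family (1 higher, 4 within, median 0.17), the miR-99/100 and miR-125 group (1 higher, 5 within, 0.26) and names linked to fragments of other RNAs (2 higher, 1 lower, 9 within, 0.08) had medians that also changed sign under other scalings. The miR-17-92 and paralogous clusters had 1 higher (0 by the read rule) and 13 within, with a median of −0.48 at percentile 1.99. The miR-221 and miR-222 (median 0.73), miR-29 (0.83), miR-130 and miR-301 (1.45) and miR-320 (1.17) groups lay within 4-fold throughout. The miR-15/16 family (4 higher, 3 within, 3.12, or 0.93 at the bounds), the miR-23/27/24 clusters (1 higher, 4 within, 1.37), the miR-148 and miR-152 family (1 higher, 2 within, 1.61) and the Hox-cluster list (2 higher, 1 lower, 2 within, 1.46, the value of miR-615-3p with 7 against 2 reads) lay at percentiles 93.4, 92.1, 89.7 and 88.6, inside the central 95% of random lists. So did the miR-34 and miR-449 family (1 lower, 2 within, −1.17, the value of miR-449a with 1 against 2 reads, percentile 13.2) and the miR-193 and miR-365 clusters (1 higher, 2 lower, 1 within, −0.43, percentile 33.2, or −2.23 at the bounds, with 0 higher by the read rule). The miR-224 and miR-452 cluster had 1 lower and 1 within (−2.17). Of these lists, miR-34a was 12.8-fold (6.44 to 28.8), miR-365 15.5-fold (9.32 to 27.6) and miR-224 7.37-fold lower (6.46 to 8.4). The neural list (2 higher, 1 lower, 3 within, 1.64) held miR-137, 35.9-fold lower (20.7 to 67.9), and the intestine, kidney and pancreas list had 1 lower and 4 within (1.17). Reported promoters of metastasis had 2 higher and 3 within (0.76), and reported suppressors 3 higher, 3 lower and 1 within (−1.24). The 4 names of the 19q13 cluster (5.49, or 1.30 at the bounds) and the 3 of the Xq27 cluster (−6.02, percentile 0.720, or −1.71 at the bounds) rested on so few reads that 0 of either passed the read rule. Of 122 passenger arms, 39 were higher, 17 lower and 66 within (0.64, or 0.20 at the bounds, with 20 higher and 12 lower by the read rule), and the list of embryonic stem cell miRNAs had 0 names past the minimum.

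In all, 505 names passed the minimum in the exosome comparison, with 148 at least 4-fold higher, 96 lower and 261 within that range in MDA-MB-231. The median log2 fold over all of them was 0.59, and 0.14 for the same names under upper-quartile scaling, which gave 135 higher and 126 lower. With 10 or more recovered reads and a counting interval excluding no difference, 89 were higher and 54 lower. Without the 11 lists of other tissues, 97 were higher and 89 lower, so most of the excess of higher names lay in those lists.

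**Figure D2:**
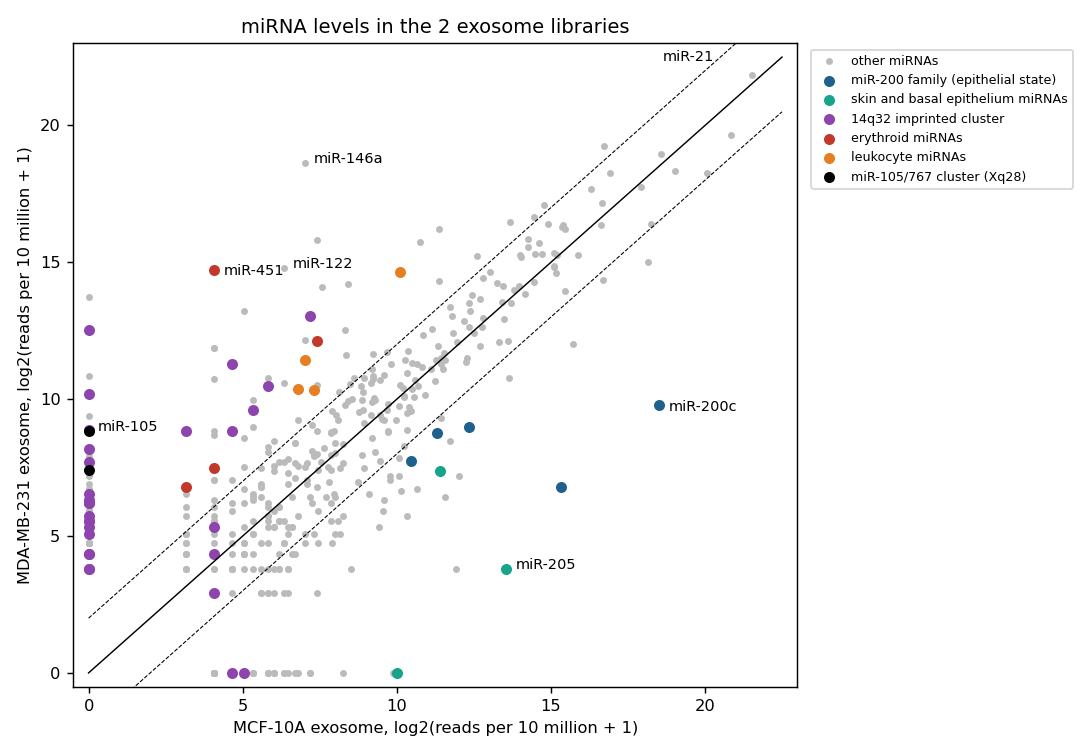
Level of each miRNA past the minimum in MCF-10A exosomes (horizontal) and MDA-MB-231 exosomes (vertical), both as log2 of reads per 10000000 plus 1, with 1 point per miRNA, a solid line at equality and dashed lines at 4-fold. The miR-200 family lies below the lower dashed line, with miR-200c at 9.78 against 18.52, and miR-146a lies far above the upper line, at 18.63 against 7.01.

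The same question asked of the cells rests on the library labelled MCF-10A cell, with its miRNAs of other tissues. The miR-200 family was again lower in MDA-MB-231, with miR-141 at 189-fold (155 to 234), miR-200c at 59.4-fold (54.4 to 64.8) and miR-200b at 10.3-fold (9.75 to 11). Of this family 4 members were at least 4-fold lower and 1 within (median −3.37, percentile 19.8). miR-205 had 0 reads in MDA-MB-231 cells and was at least 1499-fold lower, miR-203 was 500-fold lower (230 to 1367), and miR-31 (0 against 191 reads) was at least 42.9-fold lower. miR-146a was 12.2-fold higher in MDA-MB-231 cells (12.0 to 12.5), while miR-155, with 3 reads, was 659-fold lower (226 to 3210). The miR-183-96-182 cluster, lower in MDA-MB-231 exosomes, was higher in MDA-MB-231 cells (2 higher, 1 within, median 3.53, percentile 98.5), with miR-182 at 17.0-fold (16.4 to 17.7) and miR-183 at 11.6-fold (11 to 12.2). All 3 names of the miR-105 and miR-767 cluster were higher (median 5.32, percentile 100).

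Abundant members of the miR-17-92 clusters, which MYC drives, were higher in MDA-MB-231 cells, with miR-20a at 11.1-fold (10.8 to 11.3), miR-93 at 6.73-fold (6.60 to 6.86) and miR-17 at 5.66-fold (5.53 to 5.79), although the 14 names as a whole had 4 higher, 4 lower and 6 within (median 0.33). miR-30a was 16.8-fold (16.7 to 16.9), miR-100 7.84-fold (7.76 to 7.91), let-7f 5.03-fold (4.99 to 5.06) and miR-21 5.17-fold higher (5.16 to 5.18). These folds are of shares of all reads, of which 52.2% in the library labelled MCF-10A cell lay on the lists of other tissues. Over the other reads they would be smaller, and the lesser ones need not reach 4-fold. The p53-linked miR-34 and miR-449 family was lower in 6 of 6 (−5.66, percentile 14.7), with miR-34a at 54.0-fold (43.0 to 68.9) and miR-34c-5p at 48.1-fold (40.8 to 56.9). The miR-193 and miR-365 clusters were lower in 4 of 4 (−4.61, percentile 11.5), with miR-193b at 28.9-fold (25.5 to 33.0). miR-10b was 4404-fold lower (2713 to 7707), and miR-10a within 4-fold. The names with the highest folds were miR-1268 (6219-fold, 1121 to 246825, with 1 read in the other library), miR-573 (263 against 0 reads, at least 131-fold), miR-1276 (at least 61.2-fold), miR-222* (168-fold, 76.8 to 459), miR-1274a (at least 46.6-fold), miR-886-5p (103-fold, 95.1 to 113) and miR-877 (99.8-fold, 75.7 to 135).

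Most of the largest differences between the cell libraries lay in miRNAs of other tissues. miR-1 had 7 reads in MDA-MB-231 cells and was 120076-fold lower (58444 to 299509), and miR-133a, another muscle miRNA, was at least 10514-fold and miR-133b at least 5043-fold lower. miR-143 was 48496-fold (35795 to 67669), miR-145 32316-fold (8977 to 267787), miR-199a-3p 20258-fold (9332 to 55351) and miR-451 34278-fold lower (11770 to 166806). Outside these lists, miR-135a was at least 4738-fold lower. Every measured name was at least 4-fold lower in the muscle (8), mesenchymal (7), leukocyte (4), liver (3), 14q32 (46), 19q13 (47), Xq27 (19) and embryonic stem cell (3) lists. Their medians were −13.12, −14.14, −9.30, −7.21, −7.65, −9.14, −7.75 and −7.27. With names at 0 set at their bound, these became −11.82, −14.31, −8.31, −5.17, −6.00, −7.72, −5.76 and −5.23. The medians with the pseudocount lay at percentiles of 2.52 or less, with the embryonic stem cell list, at 2.52, inside the central 95%. In MDA-MB-231 cells the muscle, 14q32, Xq27 and embryonic stem cell lists held 8, 12, 8 and 1 reads in all. Their names entered through the library labelled MCF-10A cell, where the minimum against 0 reads already counts as lower. For these lists the counts say little beyond that near absence. The erythroid list had 3 lower and 1 within (−6.54, percentile 6.64), the neural list 4 lower and 3 within (−2.91, percentile 22.4), and the intestine, kidney and pancreas list 4 lower and 3 within (percentile 23.6), with miR-215 at 463-fold lower (366 to 597). The endothelial miR-126 was 77.2-fold lower (73.9 to 80.7). Reported suppressors of metastasis were lower in 7 of 8 (−5.56, percentile 1.16) and reported promoters in 6 of 8 (−3.50, percentile 20.0), and passenger arms had 32 higher, 64 lower and 47 within (−1.49, which turned positive under upper-quartile scaling).

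Of 665 names in the cell comparison, 115 were at least 4-fold higher in MDA-MB-231, 361 lower and 189 within, around a median of −2.83. Upper-quartile scaling added 2.44 to the log2 folds, before the pseudocount, and gave 240 higher and 233 lower among 628 names. Folds down to −2.44 on the log2 scale change sign with it, among them 14 of the 361 lower names, and the miR-320 family median turned from −2.28 to 0.16. Without the 11 lists of other tissues, 115 were higher and 215 lower. The remaining levels were not rescaled and are still shares of all reads, so these counts are not free of the content of those lists. The medians of the miR-221 and miR-222, let-7, miR-99/100, miR-23/27/24, miR-181 and miR-224 and miR-452 groups lay between −0.30 and 0 and were positive under all other scalings.

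The next comparison asked which miRNAs are richer or poorer in the exosomes of MDA-MB-231 than in the cells. Most abundant names were alike in both, with miR-21 at 21.85 in exosomes and 21.94 in cells, let-7a at 19.65 and 19.89, and miR-30a at 19.24 and 19.79. Richer in exosomes were let-7b, by 6.32-fold (6.23 to 6.41), and miR-1246, a name linked to a fragment of U2 small nuclear RNA, by 106-fold (102 to 111). miR-146a was 3.39-fold higher (3.35 to 3.42). All 4 members of the miR-320 family were higher, 2 of them by at least 4-fold (median 1.99, percentile 97.2), with miR-320c at 5.60-fold (4.51 to 6.96) and miR-320b at 4.24-fold (3.51 to 5.09). Names linked to fragments of other RNAs had 6 higher, 3 lower and 5 within (median 1.00, percentile 96.4), with miR-1975 at 36.9-fold (32.2 to 42.5) and miR-1979 at 7.31-fold (6.86 to 7.79).

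Poorer in MDA-MB-231 exosomes than in cells were miR-29b, 8.17-fold (7.33 to 9.14), miR-424, 6.15-fold (5.38 to 7.05), miR-218, 7.02-fold (5.65 to 8.88), miR-96, 4.90-fold (3.72 to 6.54), miR-429, 4.13-fold (2.92 to 6.06), and miR-301a, 4.30-fold (3.25 to 5.79). The miR-17-92 clusters had 1 lower and 13 within, with a median of −1.08 at percentile 1.07, and miR-20a and miR-17 were 2.03-fold (1.97 to 2.08) and 2.0-fold lower (1.93 to 2.07). The miR-200 family had 1 lower and 4 within (−1.59, percentile 3.77), and the neural list 2 lower and 4 within (−1.71, percentile 0.970). miR-105 was 1.71-fold lower in exosomes (1.33 to 2.23) and miR-767-5p 4.37-fold lower (2.94 to 6.72). Of the names with the lowest folds, miR-573 had 0 against 263 reads (at least 18.3-fold lower), miR-3200 0 against 106 (at least 7.36-fold), miR-1274a 0 against 94 (at least 6.53-fold), miR-1201 0 against 79 (at least 5.49-fold) and miR-1275 0 against 67 (at least 4.67-fold). miR-548f and miR-671-3p, at 0 in exosomes, were at least 3.41-fold and 2.64-fold lower, and miR-548o, with 1 read, was 18.2-fold lower (3.17 to 725).

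Most of the highest folds of exosomes over MDA-MB-231 cells belonged to miRNAs of blood, liver, stroma and 14q32. miR-451 was 6585-fold higher (2260 to 32058) and miR-144*, a passenger arm outside the lists, 3468-fold (961 to 28756). miR-379 had 1291 reads against 1 (6183-fold, 1108 to 244552) and miR-127-3p 913 against 1 (4372-fold, 783 to 173003). miR-223 (201 against 0 reads) and miR-150 (196 against 0) were at least 322-fold and 313-fold higher. miR-143 was 1021-fold (753 to 1425) and miR-126 28.5-fold higher (27.1 to 29.9). Outside these lists, miR-493* had 283 reads against 0, and miR-155 was 429-fold (145 to 2097) and miR-10b 806-fold higher (496 to 1413). At least 4-fold higher were 26 of 26 names of 14q32 (15 of them by recovered reads; median 6.19, or 5.85 at the bounds), 6 of 6 mesenchymal (8.07, or 7.14), 4 of 4 leukocyte (8.32, or 7.33), 3 of 4 erythroid (6.16, or 5.14), 2 of 2 liver (1 of them by recovered reads; 7.09, as miR-885-3p had only 2 against 0 reads) and 4 of 4 muscle names (2 of them by recovered reads; 5.07). The 50 listed names of 14q32 held 12 reads in MDA-MB-231 cells in all, and the 8 muscle names held 8. The 26 and 4 names past the minimum therefore entered through the exosome library alone. As 2 reads against 0 already count as higher, the direction of these counts was largely set by that entry. The erythroid, leukocyte, mesenchymal, 14q32 and muscle medians lay at percentiles 99.9, 99.9, 100, 100 and 96.5, the last inside the central 95%. Hox-cluster miRNAs had 3 higher and 2 within (3.81), and reported suppressors of metastasis, which include miR-126 and miR-335, 3 higher and 3 within (3.29).

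Of 499 names, 111 were at least 4-fold higher in MDA-MB-231 exosomes than in cells, 67 lower and 321 within, around a median of −0.09. Upper-quartile scaling gave 101 higher and 101 lower. Without the 11 lists of other tissues 61 were higher and 63 lower, and by the read rule 70 were higher and 47 lower.

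For MCF-10A, exosomes were set against the library labelled MCF-10A cell. The miR-183-96-182 cluster was higher in exosomes in 3 of 3 (median 6.05, percentile 100), with miR-182 at 18.16 against 11.29, or 117-fold (113 to 122), miR-183 at 66.3-fold (63.1 to 69.7) and miR-96 at 4.83-fold (4.28 to 5.44). let-7b was 21.6-fold (21.3 to 21.8), let-7a 7.52-fold (7.48 to 7.56), miR-200c 8.82-fold (8.70 to 8.93), miR-100 7.67-fold (7.58 to 7.77) and miR-93 8.57-fold higher (8.37 to 8.79). As in the cell comparison, folds above the library labelled MCF-10A cell would be smaller over its reads outside the lists of other tissues. The basal epithelial miR-31 was 5.88-fold higher (4.67 to 7.40) and miR-224 6.07-fold (5.69 to 6.47). Names linked to fragments of other RNAs had 6 higher, 5 lower and 2 within (1.94, percentile 99.7), with miR-1308 at 42.6-fold (40.1 to 45.1), miR-1246 at 13.1-fold (12.8 to 13.4) and miR-720 at 102-fold (52.1 to 231). miR-1268 (368 reads against 1) was 3196-fold higher (572 to 127057) and miR-222* 355-fold (161 to 979). miR-1293, miR-1254 and miR-548f, with 13, 9 and 8 reads against 0, were at least 37.8-fold, 26.1-fold and 23.3-fold higher.

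Lower in MCF-10A exosomes than in the library labelled MCF-10A cell were the miRNAs of other tissues that filled the latter. miR-145 had 0 reads in exosomes and was at least 3692-fold lower, and miR-1, with 2 reads, 72111-fold lower (19927 to 594378). miR-133a (at least 1796-fold), miR-199a-5p (at least 1641-fold), miR-133b (at least 861-fold), miR-206 (at least 739-fold) and miR-517a (at least 685-fold) were at 0 in exosomes. Every measured name was at least 4-fold lower in the muscle (8, −13.75), mesenchymal (7, −13.26), erythroid (4, −5.03), leukocyte (4, −4.85), liver (3, −7.21), 19q13 (47, −9.85), Xq27 (19, −6.81) and embryonic stem cell (3, −7.27) lists, and 44 of 46 names of 14q32 (−6.69). By the read rule these were 7 of 8 muscle, 2 of 3 liver, 45 of 47 19q13, 16 of 19 Xq27, 2 of 3 embryonic stem cell and 40 of 46 14q32 names, and all of the others. The erythroid and embryonic stem cell medians lay at percentiles 16 and 45.0, inside the central 95%, and the others at 2.07 or less. The random lists behind these percentiles hold names of the same lists, so those places do not mean small differences. All 19q13 and embryonic stem cell names had 0 reads in MCF-10A exosomes. They entered only through the library labelled MCF-10A cell and could only count as lower. With names at 0 set at their bound, the medians of the muscle, mesenchymal, liver, 19q13, Xq27, embryonic stem cell and 14q32 lists were −9.17, −11.85, −2.62, −5.27, −3.16, −2.68 and −3.65. Outside these lists, miR-135a, at 0 in exosomes, was at least 809-fold lower, and miR-99a was 166-fold (136 to 203), miR-424 808-fold (530 to 1310), miR-29c 79.6-fold (59.3 to 110) and miR-146a 76.7-fold lower (47.3 to 135). miR-105 had 0 reads against 20, a difference not detectable at this depth.

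Of 661 names, 102 were at least 4-fold higher in MCF-10A exosomes, 378 lower and 181 within, around a median of −3.27. By the read rule 69 were higher and 328 lower. Upper-quartile scaling added 2.64 to the log2 folds, before the pseudocount, and gave 227 higher and 237 lower among 625 names, with 23 of the 378 lower names turned above 0. Under it the medians of the miR-200 (−0.19), let-7 (−0.78), miR-23/27/24 (−1.85), miR-181 (−2.52), Hox-cluster (−1.60), miR-193 and miR-365 (−2.62), miR-130 and miR-301 (−1.98), miR-148 and miR-152 (−0.65) and miR-320 (−1.11) groups turned positive. The miR-200 median turned positive under all other scalings, and that of miR-148 and miR-152 under TMM and median of ratios too.

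The last comparison asked whether exosomes differ from cells in the same way in both lines. The log2 folds of exosome over cell in MDA-MB-231 and in MCF-10A had an r of −0.437 and a rho of −0.309 across 459 names, with no library in common. The r was −0.231 (rho −0.104, 394 names) without the 11 lists of other tissues. Among 391 names with 10 or more reads, 8 were at least 4-fold higher in exosomes of both lines, against 10.9 for independent lists of that size (69 and 62). These 8, named after their values were seen, were let-7b, miR-1246, miR-1308, miR-1826, miR-1979, miR-193b*, miR-423-5p and miR-629, and 4 of them are names linked to fragments of other RNAs. miR-423-5p was 6.23-fold higher in MDA-MB-231 exosomes and 20.4-fold in MCF-10A exosomes, and miR-629 7.84-fold and 4.63-fold. In exosomes of both lines 12 were lower, against 16.3 for independent lists (39 and 163), among them miR-29b, miR-218 and miR-424. Of the 11 lists of other tissues, 0 names were at least 4-fold higher in MCF-10A exosomes than in the library labelled MCF-10A cell. Such names can enter the 69 calls of MDA-MB-231 but not the 8 shared names. The 10.9 and 16.3 were not recomputed without those lists, so neither overlap is read as smaller than expected. A further 52 were higher in MDA-MB-231 exosomes and lower in MCF-10A exosomes. The opposite held for 5, named after their values were seen: miR-18a, miR-96, miR-183*, miR-374a* and miR-671-3p.

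The difference of the log2 folds (MDA-MB-231 minus MCF-10A) was highest for miR-451 (25.39), miR-143 (23.94), miR-1 (23.37), miR-127-3p (23.09) and miR-199b-3p (21.94), all miRNAs of the lists of other tissues. It was lowest for miR-548f (−12.10), miR-1268 (−11.37), miR-629* (−9.28), miR-1275 (−9.11) and miR-671-3p (−8.22), each with 2 or fewer reads in at least 1 library. Differences that involve a library at 0 reads depend on the 1 added before the log and are not bounds. Of 459 names, 202 had a difference of at least 4-fold in the direction of MDA-MB-231 exosomes, 96 in the other direction and 161 neither, around a median of 1.20. Upper-quartile scaling gave 131 and 223, and the count rule on recovered reads 128 and 97. The folds of MDA-MB-231 over MCF-10A in exosomes and in cells, which share no library either, had an r of −0.260 and a rho of −0.225 across 469 names, and −0.0256 for both (401 names) without the lists of other tissues.

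**Figure D3:**
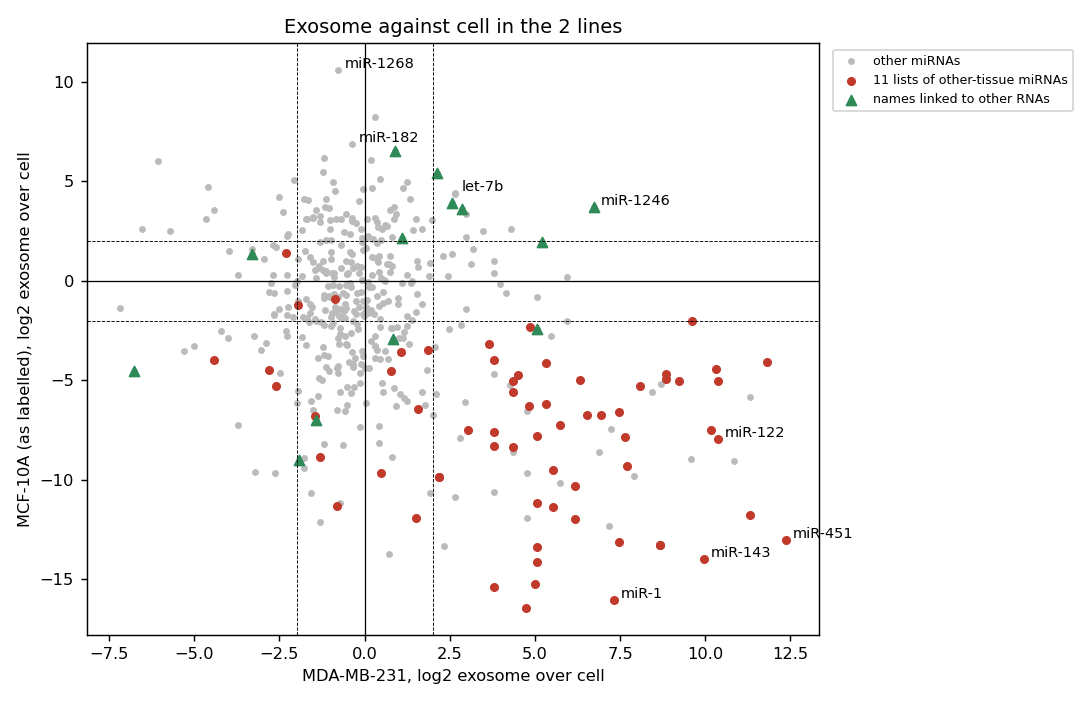
Log2 fold of exosome over cell in MDA-MB-231 (horizontal) and in MCF-10A with the library labelled MCF-10A cell (vertical), with 1 point per miRNA and dashed lines at 4-fold. Names of the 11 lists of other tissues crowd the lower right, and let-7b (2.66 and 4.43) and miR-1246 (6.73 and 3.71) lie at the upper right.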

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

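All 6 tests of explanations in this part were chosen only after the results were seen. The results below stood out because exosome over cell moved in opposite directions in the lines, or most apart, and these differences were not tested, since each group had 1 library.

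The library labelled MCF-10A cell held miRNAs of many tissues. Greater depth is argued against as their origin: thinned to the depth of MCF-10A exosomes, 126 of the 157 listed names kept 10 or more reads, against 18 in MCF-10A exosomes, and miR-143 alone held 27.1% of the reads. RNA of several other tissues, beside or in place of MCF-10A RNA, stays open: 11 of 11 lists had medians at least 4-fold above the higher of MDA-MB-231 cells and MCF-10A exosomes, also with names at 0 set at their bound (then by 9.17 on the log2 scale for muscle, 5.27 for 19q13, 2.91 for neural and 2.62 for liver names), but this restates the pattern, and MCF-10A cells that hold these miRNAs would give it too. That MCF-10A cells hold these miRNAs and do not release them stays open as well, because the share of 52.2% rests on 1 library. The cell comparison, the MCF-10A comparison of exosomes with cells, and every difference between lines below carry this doubt.

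The MDA-MB-231 exosome library held miRNAs of blood, liver and 14q32 that MDA-MB-231 cells and MCF-10A exosomes held little of. Carry-over from the library labelled MCF-10A cell as the only source is argued against by 10 of 24 such names that lay above their level there, among them miR-122, miR-127-3p and miR-379. The 19q13 names had 27 reads, where the median relative level of the 24 names, 87.3%, would give 12241. The 24 were those with 10 or more reads in MDA-MB-231 exosomes, a choice that raises the 87.3% and so the 12241. Carry-over of a part of the reads was not tested. Serum of the culture medium (fetal bovine for this line, horse for MCF-10A) or another source of blood miRNAs stays open: 95.8% (23 of 24) lay at least 4-fold above MDA-MB-231 cells, but this restates the pattern, and release by the cells would give it too. Release by MDA-MB-231 cells stays open as well: 18 of the names had at most 3 reads in the cells, and no exosome library from serum-free medium was analysed here. Of all 157 listed names, 20 had 10 or more reads in MDA-MB-231 cells themselves. Outside those lists, miR-155 (269 reads in MDA-MB-231 exosomes and 3 in the cells) and miR-10b (2692 and 16) showed the same contrast. Serum or another source, and release by the cells, stay open for them as well.

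Single miRNAs with the largest differences of exosome over cell, MDA-MB-231 minus MCF-10A, were miR-451 (25.39 on the log2 scale), miR-143 (23.94), miR-1 (23.37), miR-127-3p (23.09) and miR-199b-3p (21.94) at the upper end. At the lower end were miR-548f (−12.10), miR-1268 (−11.37), miR-629* (−9.28), miR-1275 (−9.11) and miR-671-3p (−8.22), with counting half-widths of 5.75, 2.32, 4.28, 4.74 and 4.17.

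Lists whose medians had opposite signs in the lines and lay outside the central 95% of random lists in at least 1 of them were the mesenchymal (8.07 in MDA-MB-231 and −13.26 in MCF-10A, a difference of 21.33), muscle (5.07 and −13.75, 18.82), liver (7.09 and −7.21, 14.30), leukocyte (8.32 and −4.85, 13.17), 14q32 (6.19 and −6.69, 12.88), 19q13 (1.5 and −9.85, 11.35) and erythroid lists (6.16 and −5.03, 11.19), and reported suppressors of metastasis (3.29 and −3.33, 6.62). These sizes rest in part on names at 0 reads. With those at their bound, the medians in MDA-MB-231 and MCF-10A were 7.14 and −11.85 (mesenchymal), 5.85 and −9.17 (muscle), 10.44 (from 1 name) and −2.62 (liver) and 5.85 and −3.65 (14q32). The 19q13 median in MCF-10A was −5.27 there, and its value of 1.5 in MDA-MB-231 rests on 5 names with 1 to 9 exosome reads, 0 of them higher by the read rule. The Hox-cluster list had 3.81 and −1.60 (5.41), but its MCF-10A median turned positive under upper-quartile scaling. In the other direction were the miR-183-96-182 cluster (−0.36 and 6.05, −6.41) and the miR-17-92 clusters (−1.08 and 0.21, −1.29). Other lists with opposite signs did not meet that rule or held under 3 names, among them miR-146 with miR-155 (1.76 and −4.52) and the endothelial miR-126 (4.83 and −6.31).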

How the results depend on the processing

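The alternatives named as planned were fixed before the data were examined; the read rule, the count rule on recovered reads, the lists of other tissues left out, and 1 name per shared-sequence set were added after seeing the data. Of the comparison results under alternatives, 156 lay within 1.5 times of the main value (or, for the correlations, within their spread) and 26 moved. Values of the 74 named folds under alternatives stayed within their counting interval 536 times and moved 50 times. Those of 42 list medians stayed within the spread of their members 307 times, moved 26 times and reversed 2 times. The 74 folds were picked as the highest and lowest, and the 42 medians for lying furthest out among random lists. Being large in the same data, they could hardly change sign, so the 2 reversals do not describe all lists. Medians outside the 42 changed sign too, such as let-7 between exosomes (0.09 to −0.36) and miR-320 between cells (−2.28 to 0.16), both under upper-quartile scaling. With names linked to fragments left out, the shares of reads on the 10 most abundant names moved past their Wilson interval in all 4 libraries, to 76.2%, 79.6%, 85.0% and 62.2% (main 75.1%, 79.1%, 83.2% and 62.1%, in the order MDA-MB-231 exosomes and cells, MCF-10A exosomes, library labelled MCF-10A cell). The cause was not tested unless the setting itself shows it. Upper-quartile scaling, with factors of 0.775, 0.648, 0.566 and 3.52 (MDA-MB-231 exosomes and cells, MCF-10A exosomes, library labelled MCF-10A cell), gave 240 higher and 233 lower for the cells, 101 lower for exosomes against cells in MDA-MB-231, 227 and 237 in MCF-10A, and 131 and 223 for the difference between lines. With the minimum applied after scaling, it reversed the median of passenger arms to 1.34 for the cells and 1.29 for MCF-10A exosomes against cells (main −1.49 and −1.79; 0.86 and 0.82 over the names of the main result). It moved the median fold over the names of the main result from −2.83 to −0.43 in the cells and from −3.27 to −0.67 in MCF-10A, and the medians were 0.48 and 0.33 only because 628 in place of 665 and 625 in place of 661 names then passed the minimum; TMM gave −2.22 and −2.50, and for the exosomes 0.31 in place of 0.59. For exosomes against cells in MDA-MB-231, 103 were lower with no minimum, 38 with a minimum of 50 and 149 at 2-fold. At 8-fold, a stricter size, 66 were higher in the cells, 36 lower in MDA-MB-231 exosomes and 66 higher in MCF-10A exosomes. Without the lists of other tissues, 97 were higher between exosomes, 215 lower between cells, 61 higher in MDA-MB-231 exosomes and 230 lower in MCF-10A exosomes, and the r was nearer 0, at −0.231 between the exosome-to-cell folds of the lines and −0.0256 between the line folds in exosomes and in cells. In this setting the remaining levels were not rescaled. The 215 and 230 therefore still carry the dilution of other names in the library labelled MCF-10A cell. The read rule, which drops names with few reads, gave 89 higher and 54 lower between exosomes and 70 higher in MDA-MB-231 exosomes; the count rule with TMM gave 80 and 59, 67, and 128 higher for the difference. The exosome libraries are the shallowest, and in MCF-10A exosomes 1 read is worth 7.97 per 10000000. In simulation 63.0% of names changed 8-fold were called in exosomes against cells of that line, but 90.0% between the exosomes of the lines. The lower share was therefore not set by exosome depth alone, and its cause was not tested. Exosomes and cells were compared within each line; with 1 library per group no fit with the replicate number as a block was made, and the additive model of line and fraction, which pairs the libraries by line, was not run.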

Other observations

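Both arms of some miRNA hairpins were measured, and 144 passenger arms passed the minimum in the MCF-10A comparison of exosomes with cells. There, 23 were at least 4-fold higher in exosomes, 68 lower and 53 within (20 higher and 57 lower by the read rule), with a median log2 fold of −1.79 (−0.79 at the bounds, and 0.82 under upper-quartile scaling, or 1.29 with the minimum applied after it) at percentile 100 of matched random lists, above the median of −3.27 over all names. Names with a star are in none of the 11 lists of other tissues. Without those lists the median over names was −1.57, and the passenger arms did not lie above it. In MDA-MB-231, 24 of 119 passenger arms were higher in exosomes, 18 lower and 77 within (11 higher and 15 lower by the read rule), with a median of −0.37 at percentile 12.0. The abundant passenger arms of the MDA-MB-231 libraries were miR-30a*, 2.35-fold lower in exosomes (2.27 to 2.42), miR-374a*, 4.72-fold lower (4.45 to 5.02), and miR-30e*, 2.30-fold lower (2.12 to 2.49), while miR-221* was 1.34-fold lower (1.25 to 1.43). In cells, miR-374a* was 38.1-fold higher in MDA-MB-231 than in the library labelled MCF-10A cell (35.8 to 40.6) and miR-30a* 14.3-fold higher (13.9 to 14.8).

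Within the MCF-10A exosome library, the miR-200 family summed to 426211 reads per 10000000 and the miR-183-96-182 cluster to 402748, against 2142 and 54748 in MDA-MB-231 exosomes. MDA-MB-231 cells held 4584 and 62923. Names linked to fragments of other RNAs took 3.60% of the reads of MDA-MB-231 exosomes and 2.37% of MCF-10A exosomes, against 0.609% of MDA-MB-231 cells and 0.197% of the library labelled MCF-10A cell. miR-1246 alone took 3.12% of MDA-MB-231 exosomes and 1.23% of MCF-10A exosomes. It made up 47787 of the 55270 reads on these names in MDA-MB-231 exosomes, but 2157 of 44671 in MDA-MB-231 cells. The higher share in MDA-MB-231 exosomes therefore rested mostly on this 1 name and does not describe the class as a whole. In MCF-10A exosomes it made up 15450 of 29784 reads, and 10292 of 21552 in the library labelled MCF-10A cell. There the higher share in exosomes did not rest on miR-1246 alone.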
